A study of Arabidopsis thaliana with 2 samples.

How the data were processed

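RNA of axillary buds from 2 auxin-resistant Arabidopsis lines, axr3-1 and axr1-12, was measured on 1 single-colour Affymetrix-type expression array per line. The line of each array was taken from the source name in the labels. Per the labels' protocols, total RNA was column-purified with DNase treatment, primed with an oligo(dT) primer carrying a T7 promoter, and converted to biotin-labelled cRNA by in vitro transcription. An oligo(dT) primer selects polyadenylated RNA, so signals of RNA without long poly(A) tails depend on how much of it is primed.

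The deposited values are 1 intensity per probe set on a linear scale, computed by the authors with MAS5 per the submitters' processing notes, which give no version. MAS5 combines the perfect-match and mismatch probes of a probe set into 1 signal and scales each array to a common trimmed mean. The mean of the deposited intensities after removal of the top and bottom 2% was 100 on both arrays, so the arrays had already been scaled. Detection calls were not used here. Each array holds 22810 probe sets, of which 64 are manufacturer's controls. The controls were left out of the comparison and used only to describe array quality.

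Gene names came from a table of the platform's GEO annotation, updated through gene identifiers to the symbols of the TAIR10.1 assembly. Of the 22746 probe sets used, 13513 had 1 gene in that table, 503 had several and 8730 were not listed. Probe sets with several genes or none were counted but not named. No probe set was listed for AXR1 and AXR3 (IAA17), the genes mutated in the 2 lines, nor for the bud genes DRM1 and BRC1, so their levels are not analysed here and the line of each array could not be checked against its mutated gene. The assembly's table was used only for names and for the order of neighbouring genes.

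Log2 differences were computed as axr1-12 minus axr3-1 with numpy 2.4.6 and pandas 2.3.3. The axr1-12 array was divided by the median ratio, a log2 shift of 0.021, so folds differ by about 1.48% from the ratio of the deposited intensities printed beside them. Signals below the 25th percentile of both arrays, 15.3 units, were set to that floor before log2 was taken. Probe sets whose mean log2 signal lay at or above the median passed the filter, which left 11373 probe sets, of which 6009 mapped to 1 gene each and covered 5975 genes. A gene with several probe sets was represented by the brightest. No fold is given for a gene at the floor, or below the highest of the dim bacterial control probe sets, on 1 array.

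With 1 array per line there is no estimate of biological or technical variation, so no p-value or count of significant genes is given, and no gene's difference has a standard error. The standard error given for 1 group median covers the spread among its genes only. Every difference is one between these 2 RNA samples. As a partial yardstick, the 32 genes with 2 probe sets past the filter had a root mean square disagreement of 0.37 between their log2 differences, which covers differences among probes but not among plants or hybridisations. The number of arrays limits the precision of every value below.

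Fixed before the data were examined were the floor, filter and 2-fold threshold, 31 gene lists, the alternatives to the processing and the rule for naming genes. The rule named AXR1, AXR3, DRM1 and BRC1 in any case, the 12 genes with the largest difference in each direction, among probe sets with exactly 1 gene that passed the filter and lay above the floor on both arrays and whose gene had no other such probe set of opposite sign, up to 4 genes in each direction at the floor on 1 array and above the 75th percentile on the other, and up to 4 measured members of each list that differed at least 2-fold, or, where none did, up to 2 with the largest difference. A gene named outside this rule is said to be so. Of 686 list entries, 15 were dropped because the reference names did not hold the symbol written down, 96 were on the array under 1 gene name and 42 passed the filter, which is what a measured gene means below. The median of a list with at least 5 such members was placed among 10000 random lists of the same size matched on mean signal in 20 bins. It was said to stand apart below percentile 2.5 or above 97.5, which describes these 2 arrays and is not a test of the lines. The minimum of 5 members was set after the small number of listed genes became known, and left 2 of the 31 lists.

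Groups added after the files were seen were the genes of the plastid and mitochondrial genomes, nuclear genes with plastid terms in their names, 2 lists of amino acid breakdown genes, and 16 families sharing a symbol stem with at least 6 members. Alternatives were the deposited scale, quantile and loess scaling (statsmodels 0.14.6, span 0.3), no floor or a pseudocount, other filters, plain _at probe sets only, a 3-fold threshold and the mean over probe sets of a gene. The procedure was tested on simulated data built on these arrays with a log2 noise SD of 0.44 over 5975 genes. It recovered 99% of 200 genes changed 4-fold past the 2-fold threshold, and 2.25% of unchanged probe sets also passed it. That noise SD is the spread of the observed differences themselves, so the share is no estimate of the error of the arrays. A list of 12 genes shifted by 0.6 came out at a median of 0.59 and percentile 99.98, and 4 of 100 unshifted lists stood apart. Figures were drawn with matplotlib 3.10.9.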

Results

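The series compared gene expression in axillary buds of 2 Arabidopsis thaliana lines in the Col-0 background that carry ethyl methanesulfonate-induced mutations, and its title frames the comparison as one of dormant with active axillary meristems. The axr3-1 line carries a gain-of-function allele of AXR3, also called IAA17, a repressor of auxin-responsive transcription, and shows strong apical dominance. The axr1-12 line carries a loss-of-function allele of AXR1, a subunit of the enzyme that activates the ubiquitin-like protein RUB for auxin signalling, and branches more than the wild type. The labels describe the buds of both lines in the same words, as elongated to about 2 mm, and which line was taken as dormant is not given in the sources used here. Plants were grown on compost at 21 °C under 16 h of light and 8 h of dark, after 3 days of cold treatment of the sown soil. One array was hybridised per line, so the differences below have no replicate check.

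The median deposited signal was 51.8 on the axr3-1 array and 52.3 on the axr1-12 array, with upper quartiles of 127.0 and 132.5. The bright end was lower on the axr1-12 array, with a highest signal of 8062 in axr3-1 and 6068 in axr1-12 and mean signals of 143 and 132. Over the 11373 probe sets that passed the signal filter, log2 signals correlated between the arrays at r = 0.905, a value across probe sets, which are not independent replicates. Of these probe sets, 78.6% differed by less than 1.5-fold. The ratio of 3′ to 5′ signal, a sign of RNA integrity, was taken from control probe sets for actin, GAPDH and ubiquitin. The ratio of the first actin set was 4.30 in axr3-1 and 4.91 in axr1-12, and that of the second ubiquitin set was 2.29 and 1.75. Over 6 such pairs the log2 ratios of axr1-12 minus axr3-1 had a median of -0.03 and ranged from -0.39 to 0.20. The control probe set for cytosolic 25S ribosomal RNA gave 1101 units in axr3-1 and 549 in axr1-12. All 18 probe sets of the hybridisation spikes had a lower signal in axr1-12, by a median log2 difference of -0.61.

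The comparison asks which genes differ between buds of the 2 lines. All 62 plastid-encoded genes past the filter had a lower signal in axr1-12 than in axr3-1 buds, 28 of them at least 2-fold, and the median difference was 1.93-fold. After quantile scaling 57 were lower and 3, atpE, psaJ and psbM, were slightly higher. The rest had the same rank on both arrays, and quantile scaling gives equal ranks equal values. The number at least 2-fold lower was 22 after quantile and 23 after loess scaling. Nuclear genes for light harvesting and photosystem subunits were lower in axr1-12 by a median of 1.90-fold. AT4G21870 was 13.3-fold higher in axr1-12, the transcription factor gene ZAT10 4.86-fold higher and the dehydrin gene COR47 4.16-fold higher. In total, 352 probe sets were at least 2-fold higher in axr1-12 and 373 were at least 2-fold lower, together 6.37% of those past the filter. At least 4-fold differences numbered 41 higher and 21 lower.

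**Figure D1:**
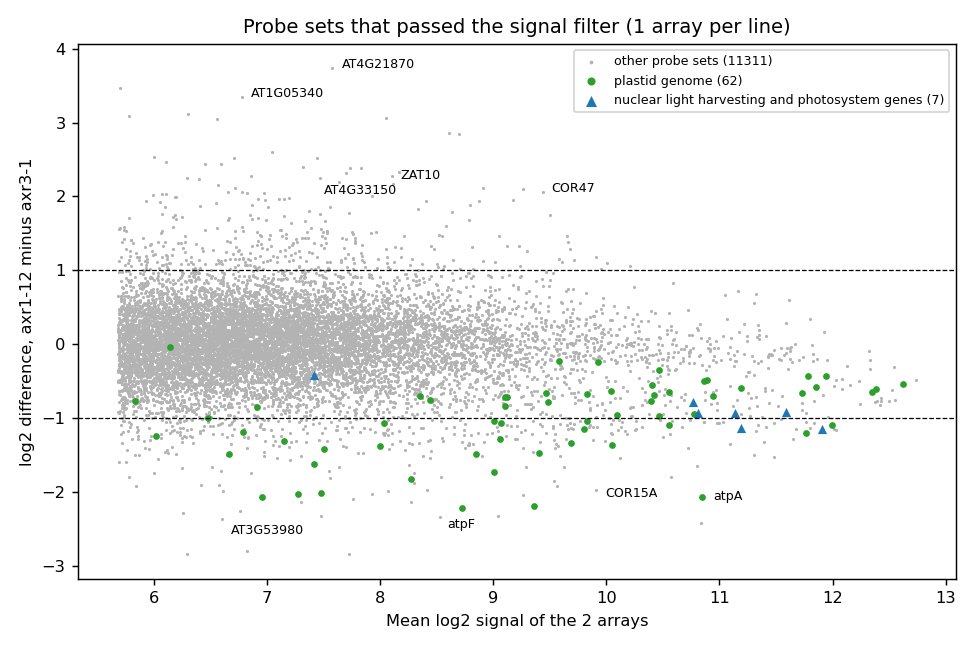
Log2 difference of axr1-12 minus axr3-1 against the mean log2 signal of both arrays for the 11373 probe sets past the filter, with dashed lines at 2-fold. All 62 plastid-encoded genes (green) lie below 0, which held for 57 of them after quantile scaling, and the 7 nuclear light harvesting and photosystem genes (blue triangles) lie below 0 as well, 6 of them at high signal.

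The 12 genes with the largest higher signal in axr1-12, among those with a name here, were nuclear. AT4G21870 had 52.4 units in axr3-1 and 707 in axr1-12. AT1G05340 was 10.1-fold higher, from 34.5 to 354 units. AT1G68440 had 156 units in axr1-12, and its 26.6 units in axr3-1 lay below the highest of 27 dim bacterial control probe sets, 29.4 units, so no fold is given. ZAT10, also named STZ, a zinc finger repressor induced by salt, cold and wounding, was 4.86-fold higher, from 124 to 614 units. AT4G33150, the LKR/SDH gene for the enzyme that begins lysine breakdown, was 4.77-fold higher, from 81.1 to 392 units. MCCA, a subunit of the methylcrotonyl-CoA carboxylase of leucine breakdown, was 4.18-fold higher, from 53.8 to 228 units. COR47, a cold- and dehydration-induced dehydrin, was 4.16-fold higher and among the brighter of these genes, at 340 and 1433 units. ARR16, listed as RR16, a type-A response regulator of cytokinin signalling, was 4.09-fold higher but dim, at 33.2 and 138 units. AT3G49790 was 4.47-fold higher, and AT2G05540, AT1G65490 and AT2G23450 were 4.03-, 3.93- and 3.91-fold higher. One further gene, AT2G31945, lay at the floor in axr3-1 and at 151 units in axr1-12. Among probe sets not listed in the name table, the largest higher signals went from 15.6 to 175 units and from 26.8 to 234 units. Both lay below 29.4 units in axr3-1, so no fold is given.

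The 12 genes with the largest lower signal in axr1-12, among those with a name here, were 6 plastid genes and 6 nuclear genes. Among probe sets not listed in the name table the largest differences were larger. They were 7.17-fold lower, from 568 to 80.3 units, and 7.12-fold lower, from 209 to 29.8 units. AT3G53980 was 5.15-fold lower, from 220 units in axr3-1 to 43.3 in axr1-12. AT3G28220 was 4.77-fold lower, from 237 to 50.4 units. AT1G12845 was 4.38-fold lower, and AT5G03350 was 4.37-fold lower. XTH16, a xyloglucan endotransglucosylase/hydrolase of the cell wall, was 3.94-fold lower, from 534 to 138 units. COR15A, a cold-regulated chloroplast protein gene, was 3.91-fold lower, from 1898 to 492 units, the direction opposite to that of COR47. AT5G59250 lay at the floor in axr1-12 and at 132 units in axr3-1.

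**Figure D2:**
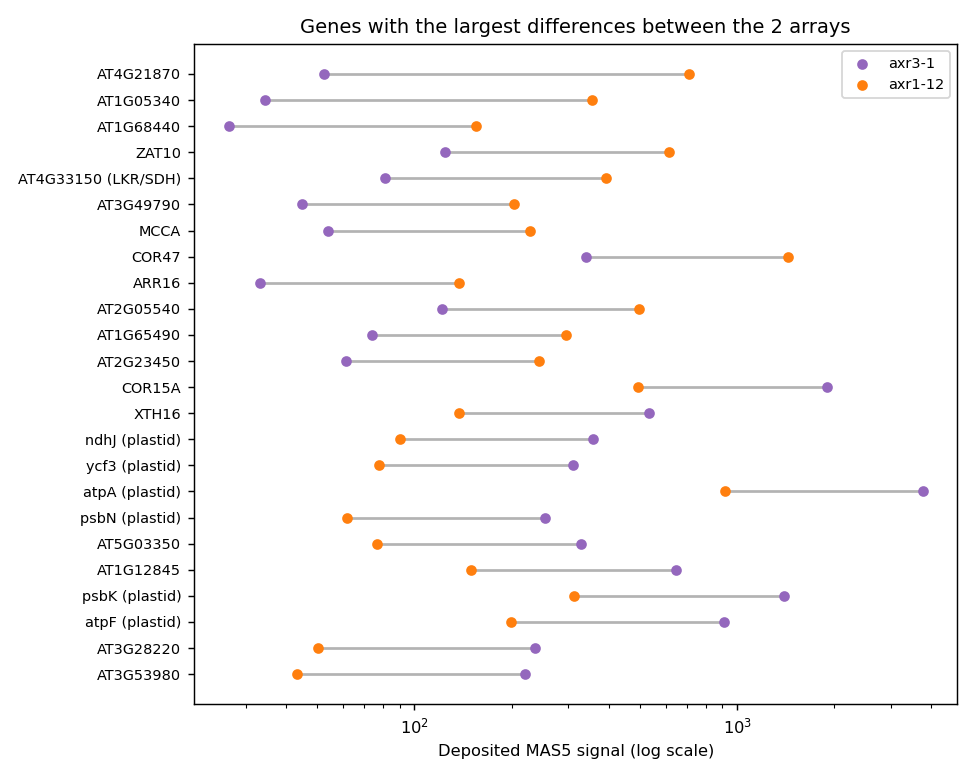
Deposited MAS5 signal, on a log scale, on the axr3-1 array (purple) and the axr1-12 array (orange). Shown are the 12 genes with the largest difference in each direction, among those with a name here. AT4G21870 at the top was 13.3-fold higher in axr1-12 and AT3G53980 at the bottom 5.15-fold lower.

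The ranges of the plastid gene groups overlapped, and differences between groups were not tested. The 5 ATP synthase genes had a median log2 difference of -1.46. Of these, atpF was 4.63-fold lower in axr1-12, from 907 to 199 units, and atpA was 4.17-fold lower, from 3760 to 915 units, whereas atpB was 1.46-fold lower. After quantile scaling atpE was slightly higher, and atpB had no difference only because its rank was the same on both arrays. The 8 NDH genes had a median of -1.16, led by ndhJ at 4.02-fold lower. The 3 RNA polymerase genes ranged from -1.36 to -0.72. The 5 photosystem I genes had a median of -1.04, and of -0.60 after quantile and -0.69 after loess scaling. The 14 ribosomal protein genes had a median of -0.92, and rps15 was 1.03-fold lower. The 15 photosystem II genes had a median of -0.70, with psbK 4.53-fold lower, psbN 4.19-fold lower and psbJ 1.16-fold lower, and the 4 cytochrome b6f genes ranged from -0.97 to -0.64. Among the remaining genes ycf3, a photosystem I assembly factor, was 4.06-fold lower and rbcL, the large subunit of Rubisco, was 2.09-fold lower. The plastid median, a log2 difference of -0.95, lay below all 10000 matched random lists, whose central 95% ran from -0.23 to 0.01. Random lists draw genes independently, whereas plastid genes share 1 genome and need not vary independently. This placement is therefore no measure of how unusual the median is. The grouping of genes by genome was made after the data had been seen, and the plastid genes named beyond the 6 with the largest differences were also chosen then. The hybridisation spikes and the brightest probe sets were lower in axr1-12 as well. The 25S ribosomal RNA control, also an RNA without a long poly(A) tail, was 2.04-fold lower in axr1-12, whereas the 8 mitochondrion-encoded genes past the filter had a median log2 difference of -0.10 at percentile 30.0.

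The list of nuclear light harvesting and photosystem genes was fixed before the data were examined, and 7 of its genes were measured. All 7 were lower in axr1-12 and 2 were at least 2-fold lower. LHCB4.1, an antenna protein of photosystem II, went from 5706 to 2620 units, 2.21-fold lower, and PSAE-1, a photosystem I subunit, from 3473 to 1604 units, 2.20-fold lower. The list median of -0.93 stood apart at percentile 0.655 of matched random lists. The 20 bins hold equal numbers of genes, so the brightest spans a wide range of signal and the match is coarse there. After quantile scaling the median was -0.55 and after loess scaling -0.63, and neither LHCB4.1 nor PSAE-1 then reached 2-fold. With the plastid-encoded genes and these 7 left out, bright probe sets also tended to be lower in axr1-12. Their median log2 difference was -0.30 over the 128 with a mean log2 signal of 11 or more, and -0.17 from 10 to 11. Nuclear genes with plastid terms in their names, such as PORB and AT4G01150, were still among the 128. Of the 128, 84 were not listed in the name table, so further photosynthesis genes may be among them.

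**Figure D3:**
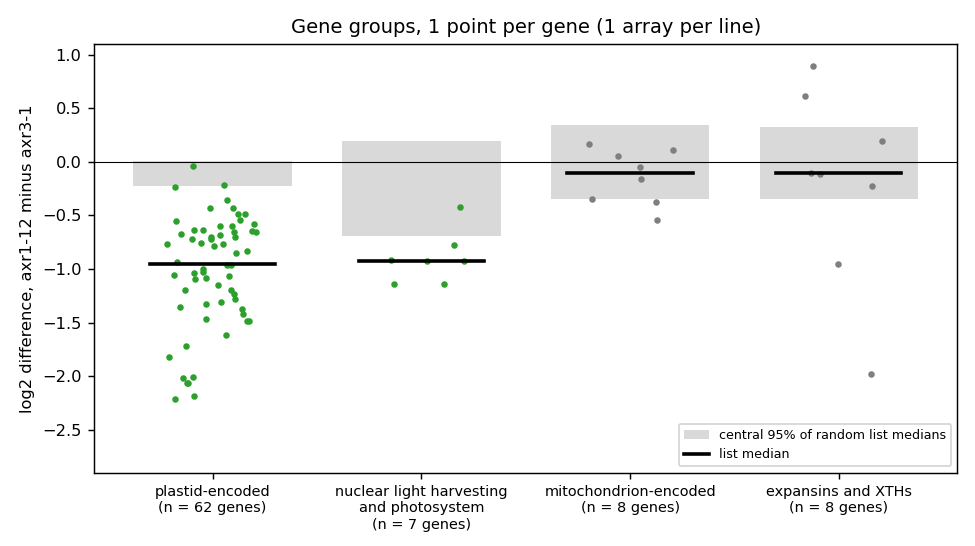
Log2 difference of axr1-12 minus axr3-1 per gene (points) in 4 groups, with the group median (bar) and the central 95% of medians of matched random lists (grey box). The medians of the plastid-encoded genes (-0.95) and of the nuclear photosynthesis list (-0.93) lie below their boxes, and those of the mitochondrion-encoded genes (-0.10) and of expansins and XTHs (-0.11) lie within them.

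The expansin and XTH list, enzymes and proteins that loosen or remodel cell walls, had 8 measured genes, of which 1, XTH16, differed 2-fold. Its median of -0.11 lay at percentile 28.4 and so did not stand apart.

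The remaining lists had at most 4 measured genes each, too few for a statement on the list. Log2 differences smaller than 0.37 in either direction lie within the disagreement between probe sets of a gene, so their direction is not interpreted. Among these lists they include IAA18, YUC2, MCM7, SIM, LAS, PHV, IRX10, BZIP53, AT1G77750, the mitosis gene AUR2 and the 4 measured histone genes. Of the bud dormancy and sugar starvation list only AKINBETA1, a regulatory subunit of the starvation-responsive kinase SnRK1, was measured, and it was 2.16-fold higher in axr1-12, at 352 and 770 units. Among auxin genes, GH3.5, which conjugates auxin to amino acids, was 1.94-fold higher in axr1-12, IAA18 of the Aux/IAA family was 1.11-fold higher and YUC2, an auxin biosynthesis gene, was 1.08-fold lower. Of the abscisic acid list only COR47 and COR15A were measured, and they differed in opposite directions. ZAT10 was the single measured gene of the touch, wound and cold list, and ARR16 that of the type-A response regulators. The gibberellin receptors GID1A and GID1B were 1.43- and 1.40-fold higher in axr1-12.

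The fixed lists on DNA replication, histones, mitosis, and cyclins and their inhibitors held 16, 34, 22 and 14 entries. Of all measured genes, 5.44% differed at least 2-fold, so a count over the few measured here cannot show whether cell division differed. The 9 measured genes of these lists differed by less than 2-fold. Among them the mitotic kinases AUR3 and AUR1 were 1.46- and 1.36-fold lower in axr1-12, the replication helicase subunit MCM7 was lower by a log2 difference of -0.27, and the histone H2B genes HTB2 and HTB11 were 1.17- and 1.16-fold higher. Of the 4 measured histone genes 2 were higher and 2 lower, and of the 3 measured mitosis genes 1 was higher and 2 were lower. SIM, an inhibitor of cyclin-dependent kinases, was 1.06-fold higher. Of the meristem regulators, LAS, which is needed to form axillary meristems, was 1.15-fold lower and PHV 1.13-fold higher. AGL42, a MADS-box gene of the flowering list, was 2.42-fold higher in axr1-12, from 69.3 to 170 units. Among markers of other tissues, IRX10 of secondary walls was 1.19-fold lower and the anther regulator AMS was 1.40-fold higher. GI of the circadian clock was 1.43-fold lower, BZIP53 of the sugar list 1.05-fold lower, and AT1G77750, the single locus matched for ribosomal proteins, 1.17-fold lower. Over all lists, 42 genes were measured, of which 5 were at least 2-fold higher in axr1-12 and 4 at least 2-fold lower. After quantile or loess scaling the counts were 6 and 2, since GH3.5 then reached 2-fold and LHCB4.1 and PSAE-1 no longer did. No measured gene was left for the lists of strigolactone, SAUR, RUB conjugation, cytokinin metabolism, epidermis and stomata, senescence, jasmonate, salicylate, heat shock and flavonoid genes.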

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

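The test of array scaling in this part was chosen after the result had been seen, and the tests on mitochondrial and nuclear genes were written down beforehand. Control probe sets outside the comparison gave signal above the level of the 27 bacterial control probe sets without high signal, whose highest value on either array was 29.4 units. The 25S ribosomal RNA control gave 1101 units in axr3-1 and 549 units in axr1-12. The 18 probe sets of the 4 hybridisation spikes all had a lower signal in axr1-12, by a median log2 difference of -0.61 with a range from -0.82 to -0.24.

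The 25S control differed in the same direction as the plastid-encoded genes. The tables argue against intensity-dependent scaling as the whole cause of the plastid difference, because its median stayed at -0.74 or lower under both quantile and loess scaling. More carry-over of RNA without long poly(A) tails on the axr3-1 array could produce both the 25S and the plastid difference, yet it would also be expected to lower mitochondrial transcripts, whose median was -0.10 with a bootstrap SE of 0.14 over 8 genes. That value lies above the -0.5 the explanation called for but not clear of -0.2, so this explanation stays open. Fewer or less active chloroplasts in the axr1-12 buds is a candidate explanation that also predicts lower nuclear photosynthesis transcripts, which are polyadenylated, and their median was -0.93 over 7 genes, or -0.55 after quantile and -0.63 after loess scaling. It gives no account of the lower cytosolic 25S control, nor of the hybridisation spikes, which are not bud RNA and had a median of -0.61. A difference between the lines, between bud stages, between 2 individual RNA samples or between the 2 hybridisations cannot be separated with 1 array per line.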

How the results depend on the processing

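Both counts at 2-fold stayed within 1.5 times their values of 352 higher and 373 lower under the deposited scale, quantile and loess scaling, no floor, a pseudocount, a filter at the 67th percentile and plain _at probe sets, and, as an alternative chosen after seeing the data, without plastid-encoded genes (352 and 345). Without a filter they were 709 and 738, over 22746 in place of 11373 probe sets, and at 3-fold they were 86 and 53. The photosynthesis list median of -0.93 became -0.55 under quantile and -0.63 under loess scaling, and the plastid median of -0.95 became -0.74 and -0.75. That of all 18 nuclear genes with plastid terms in their names, -0.79, became -0.57 and -0.61. All of these medians still stood apart from random lists, and the cause of the moves was not tested. Of 66 alternative values of 8 list medians, 60 moved by less than the SD of random list medians, and the ATG family was the only list to change whether it stood apart. Its median of 0.30 did not, while 0.41 under quantile and 0.40 under loess scaling did, and so did 0.32 over a wider autophagy list, all alternatives chosen after seeing the data. None of 230 alternative values of the 46 genes named by the rule, under the scalings, no floor and a pseudocount, changed sign. Among plastid genes outside the rule, atpE, psaJ and psbM changed sign under quantile scaling, to 0.07, 0.06 and 0.13. Of the 230 values, 5 moved by more than the disagreement between probe sets of a gene. These were LHCB4.1 under both scalings and ARR16, AT1G05340 and AT1G68440 with a pseudocount. The list of amino acid breakdown genes not seen before had too few members for a value with the filter at the 67th percentile. No replicate could be left out and no regrouping of samples exists with 1 array per line. No paired analysis was possible because each line has 1 array. Signal over background limits the dimmest genes, for which no fold is given.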

Other observations

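The tests of RNA integrity and of array labels were chosen after the result had been seen, and those of further pathway genes and of neighbouring genes before. COR15B, SRC2, PORB, ARL, SKP2A and the ATG family were singled out after their values were seen. COR15B, the chromosomal neighbour and close relative of COR15A, was 3.76-fold lower in axr1-12, from 1464 to 395 units, like COR15A itself, and signal shared between the pair was not tested. SRC2, named for a cold-regulated gene of soybean, was 3.37-fold higher in axr1-12, like COR47. PORB, which makes chlorophyllide in the light, was 2.87-fold lower, from 4837 to 1709 units. Leaving out the 5 genes shared with the fixed photosynthesis list, 11 of 13 nuclear genes with a plastid term in their names were lower in axr1-12. Their median log2 difference was -0.70 at percentile 0.02, and -0.59 after quantile and after loess scaling. ARL, an ARGOS-like growth gene, was 2.96-fold higher, and SKP2A, an F-box protein gene, was 2.54-fold higher.

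All 8 measured genes of the autophagy family ATG were higher in axr1-12 under each scaling, with a median log2 difference of 0.30 at percentile 96.7. The percentile was 99.4 after quantile and 99.3 after loess scaling, and 98.6 over the 11 genes with any autophagy symbol or synonym, all 11 higher, so whether the family stood apart depended on scaling and on its members. Most of these genes are ATG8 relatives, whose probe sets need not be independent. ATG8B was 2.65-fold higher and ATG8E 2.49-fold higher. None of the 16 families stood apart with median scaling, where 0.8 would by chance, and the other families were not examined under other scalings.

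Among the genes higher in axr1-12, 5 of amino acid and purine nitrogen breakdown were noticed, namely LKR/SDH, MCCA, IVD of leucine breakdown at 3.21-fold, ALN, which degrades the purine product allantoin, at a log2 difference of 1.68, and DELTA-OAT of ornithine breakdown at 2.72-fold. If this were a change of the wider pathways, as in carbon-starved tissue, other members would be expected to be higher too. The 7 other measured members had a median log2 difference of 0.044 at percentile 64.8, from ETFALPHA at -0.61 to D2HGDH at 0.86, with MCCB at 0.48, and with a spread of 0.21 over random lists a wider change stays open. For RNA integrity, the 3′ to 5′ ratios of control genes differed by a median log2 value of -0.027, but the ratios of middle to 5′ signal differed by a median of -0.15 over 4 pairs, from -0.62 for the second actin set to 0.13, so a difference in integrity stays open. Arrays labelled with the wrong line could not be checked, because 0 probe sets of the 2 mutated genes have a name here.

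AT1G05340 had the second largest higher signal in axr1-12 among genes with a name here. It lies close to AXR1 in the gene order of the TAIR10.1 assembly. A hypothesis was that a segment around AXR1 differs between the lines. Within 25 loci on each side of AXR1, 1 of 14 measured genes, AT1G05340 itself, differed at least 2-fold. This is a share of 7.14% (exact 95% binomial interval 0.18% to 33.9%) against 5.44% of all measured genes. Because AT1G05340 prompted the hypothesis, its own count was fixed in advance, and no other measured gene there differed 2-fold. The count is too small to decide. Around AXR3, 1 of 11 measured genes differed at least 2-fold.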
